A study of Mus musculus with 18 samples.

How the data were processed

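Small RNAs of mouse cerebellum and hippocampus were sequenced in 18 libraries, 3 for each of 6 groups. Groups were read from the sample labels and matched to the library columns of the deposited tables by genotype, tissue and number. Per the labels' protocols, total RNA was isolated with Trizol from flash-frozen tissue of male mice aged 1 month on the C57BL/6J strain, libraries started from 5 ug of total RNA, and small RNAs of 18 to 32 nt were selected. RNA integrity numbers ran from 8.5 to 9.5. The submitters' processing notes name cutadapt, without a version, and DESeq2 1.10. The method that assigned reads to miRNAs, the miRNA annotation and the genome build of the counts are not given in the sources used here.

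The authors deposited 4 tables, each comparing a mutant group with the WT libraries of its tissue and each listing 1841 mature miRNAs. The deposited counts are whole numbers of reads per miRNA and library, taken as raw counts because each second set of library columns equals them times a factor per library. That second set, marked as normalised per the file headers, was read as signal, the count divided by a size factor set within each table. The log2 fold changes and their standard errors are the authors' values for mutant over WT, per the file headers. The p-value columns, raw and adjusted, are the authors' own test, per the file headers, and were used here as an alternative source of calls. The WT cerebellum counts were identical in the 3 cerebellum tables and entered once.

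Counts were analysed in R 4.3.3 with edgeR 4.0.16. miRNAs were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and groups were compared by the robust quasi-likelihood F-test (QL) with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. Each mutant group was compared with the WT libraries of its tissue in a fit of those 6 libraries. The double mutant against each single mutant, and the interaction of both mutations, were contrasts in a fit of the 12 cerebellum libraries. The difference of the CyrKO effect between tissues and the WT tissue difference were contrasts in a fit of the 12 WT and CyrKO libraries. Levels are CPM, the count of a miRNA over its library's total of miRNA reads, without TMM and on the usual CPM scale, with their SD over 3 libraries. Ratios of guide to passenger strand were compared on the log2 scale by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. Shares of reads carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. In the text the shares are given with their SD over 3 libraries.

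The miRNAs named, the 24 lists and the alternatives were chosen before the data were examined. Named in each comparison were all strands of miR-7 and miR-671, the 10 risen and 10 fallen miRNAs with the largest change among those past the threshold whose groups of libraries did not overlap, up to 4 members per list, and, where fewer than 5 passed, all that passed and the 3 with the lowest p among the rest. For the WT tissues a mean of at least 100 CPM in 1 tissue was also required. Named after their values were seen were miR-411-3p and miR-379-3p in the hippocampus and the miR-142 strands. The lists cover miR-7 guide and passenger strands, miR-671 strands, other reported targets of target-directed miRNA degradation, neuronal, activity-regulated, oligodendrocyte, immune, erythroid, vessel, choroid plexus, epithelial miR-200, sensory miR-183, endocrine, Hox and muscle miRNAs, the miR-379/410 and miR-127 with miR-433 clusters, let-7, miR-17~92 and relatives, miR-29, miR-30, miR-181, and entries that overlap rRNA. Lists with at least 3 tested members were tested by camera on voom values in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and by fry. Medians given with a camera result are of the voom log2 changes and can differ from the edgeR values given for members. List counts were taken over all tested miRNAs and adjusted over the list alone. let-7a-5p, let-7c-5p, miR-30b-5p, miR-30c-5p, miR-133a-3p and some other list members were not analysed here.

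The full procedure was tested on simulated data, negative binomial counts drawn at the mean level and dispersion of each miRNA in each comparison. Of simulated 2-fold changes it recovered 89.1% for CyrKO against WT in cerebellum, 87.7% in hippocampus, 72.7% for Cdr1as671 against WT and 90.9% for the double mutant against WT. At 1.5-fold the shares were 52.2%, 65.7%, 19.4% and 65.2%. For the interaction they were 56.7% at 2-fold and 13.6% at 1.5-fold. For the tissue difference of the CyrKO effect they were 66.2% and 25.4%. The simulations changed many miRNAs at once and called 123 to 170 in the comparisons with WT, against 4 to 17 in the real data. The adjusted threshold is stricter where fewer miRNAs change, so these shares do not give the power at the real counts.

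Alternatives were DESeq2 1.42.0, RLE size factors, library totals alone, leaving out the 10 most abundant miRNAs, no low-count filter, a mean of at least 10 CPM, the replicate number as a block, 12 libraries in 1 fit, the authors' table, and leaving out each library in turn. Added after seeing the data were the mean of the erythroid miRNAs or of the choroid plexus miRNAs as a covariate, and leaving out Cdr1as671 libraries 1 and 2. For the correlation of changes between comparisons the erythroid covariate was also fitted within the 6 libraries of each comparison. The labels give the groups the same replicate numbers without saying what a number marks. Deviations of equally numbered libraries from their group means correlated across miRNAs at r = 0.49, 0.31 and 0.27 for WT and the double mutant in cerebellum, every pair above 0.1, so those libraries were also treated as pairs. The other pairs of groups did not meet this rule. The replicate block was run in every comparison all the same, so outside WT and the double mutant a call lost with it does not rest on a shown pairing. Positions are those of GENCODE M21 on GRCm38, matched by hairpin name, since the tables name no build. Complementarity to the annotated Cyrano transcript was scored for hairpin arms matched to 95.4% of the miRNAs tested in CyrKO against WT cerebellum. An arm is either side of a hairpin cut at its middle, flank and loop included, so longer hairpins have longer arms.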

Results

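Small RNAs were sequenced from mouse brain in 18 libraries that form 6 groups of 3 biological replicates. Cerebellum came from wild-type mice (WT), mice without the long noncoding RNA Cyrano (CyrKO), mice in which the miR-671 site of the circular RNA Cdr1as is mutated (Cdr1as671), and double mutants (CyrKOCdr1as671). Hippocampus came from WT and CyrKO mice. Libraries held from 8591172 to 15305829 miRNA reads, and 1042 to 1174 miRNAs had a read. The neuronal miR-124-3p was the most abundant miRNA in each library, at 10.8% to 22.9% of the reads. Log2 levels of replicate libraries correlated across miRNAs at r = 0.986 to 0.998, while the chi-square per degree of freedom between replicates, 37.8 to 534, lay far above counting error. Neither Cyrano nor Cdr1as was measured in these libraries, so the genotypes were not checked on the targeted RNAs.

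Cyrano carries a site with extensive pairing to miR-7, and the comparison of CyrKO with WT cerebellum asks which miRNAs depend on it. Both miR-7 guide strands, miRNAs of neurons and endocrine cells, rose far more than any other miRNA. miR-7a-5p rose 40.5-fold, from 496 ± 52.9 CPM in WT to 20026 ± 838 CPM in CyrKO (SD, n = 3 each), and miR-7b-5p rose 47.2-fold, from 173 ± 25.3 to 8136 ± 574 CPM. miR-671-5p, the miRNA that directs slicing of Cdr1as, rose 1.85-fold, from 122 ± 9.55 to 225 ± 14.1 CPM. Strands from 3 hairpins of the imprinted Dlk1-Dio3 region also rose, miR-409-3p 2.84-fold from 27.5 ± 3.05 CPM, miR-411-3p 2.01-fold from 188 ± 13.4 CPM and miR-379-3p 1.84-fold from 104 CPM. These 6 of 668 tested miRNAs passed edgeR's QL test, with adjusted p from 2.52e-11 for miR-7a-5p to 0.000376 for miR-379-3p, and each was higher in all 3 CyrKO libraries than in any WT library. The log2 changes were 5.34 (SE 0.11) for miR-7a-5p and 5.56 (SE 0.13) for miR-7b-5p. No miRNA fell by edgeR or DESeq2 (0 of 668 in edgeR, with 16 miRNAs at an unadjusted p under 0.05, 8 of them lower), but 1 was called lower in edgeR with no low-count filter, with the replicate block, with 12 libraries in 1 fit and with the erythroid covariate. Reads of miR-7a-5p and miR-7b-5p, which have nearly the same sequence, and of the similar 3p strands of hairpins 379 and 411, may be split uncertainly between them.

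The other strands of the miR-7 and miR-671 hairpins stayed near their WT level in CyrKO cerebellum. The log2 changes were −0.0045 (SE 0.10) for miR-7a-1-3p, 0.04 (SE 0.20) for miR-7a-2-3p, −0.09 (SE 0.30) for miR-7b-3p and −0.14 (SE 0.12) for miR-671-3p, with an adjusted p of 0.999 for each, and the sign for miR-7a-1-3p changed with the scaling. The log2 ratio of miR-7a-5p to miR-7a-1-3p went from 0.43 ± 0.12 in WT to 5.79 ± 0.24 in CyrKO, and that of miR-671-5p to miR-671-3p from 2.52 ± 0.14 to 3.55 ± 0.03. The libraries of the 2 groups did not overlap in either ratio (exact two-sided permutation p = 0.1, the smallest possible for 3 against 3, adjusted p = 0.107 over 16 ratio tests). The hairpin Mir7-1 lies on chromosome 13 at 58392779 to 58392886 within an intron of Hnrnpk, Mir7-2 on chromosome 7 at 78888277 to 78888373 and Mir7b on chromosome 17 at 56242988 to 56243098. Mir671 lies on chromosome 5 at 24592114 to 24592211 in an exon of Chpf2, and Mir379, Mir411 and Mir409 lie on chromosome 12 at 109709060, 109710175 and 109743158. Cyrano is annotated as 1700020I14Rik on chromosome 2 at 119594297 to 119607502. Of the 35 tested members of the miR-379/410 list, 1 rose (miR-409-3p), over all tested and adjusted over the list alone. That list holds the 5p strands of hairpins 379 and 411 and not their 3p strands. No list differed from the other miRNAs by camera, and the lowest adjusted p was 0.109, for this list.

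**Figure D1:**
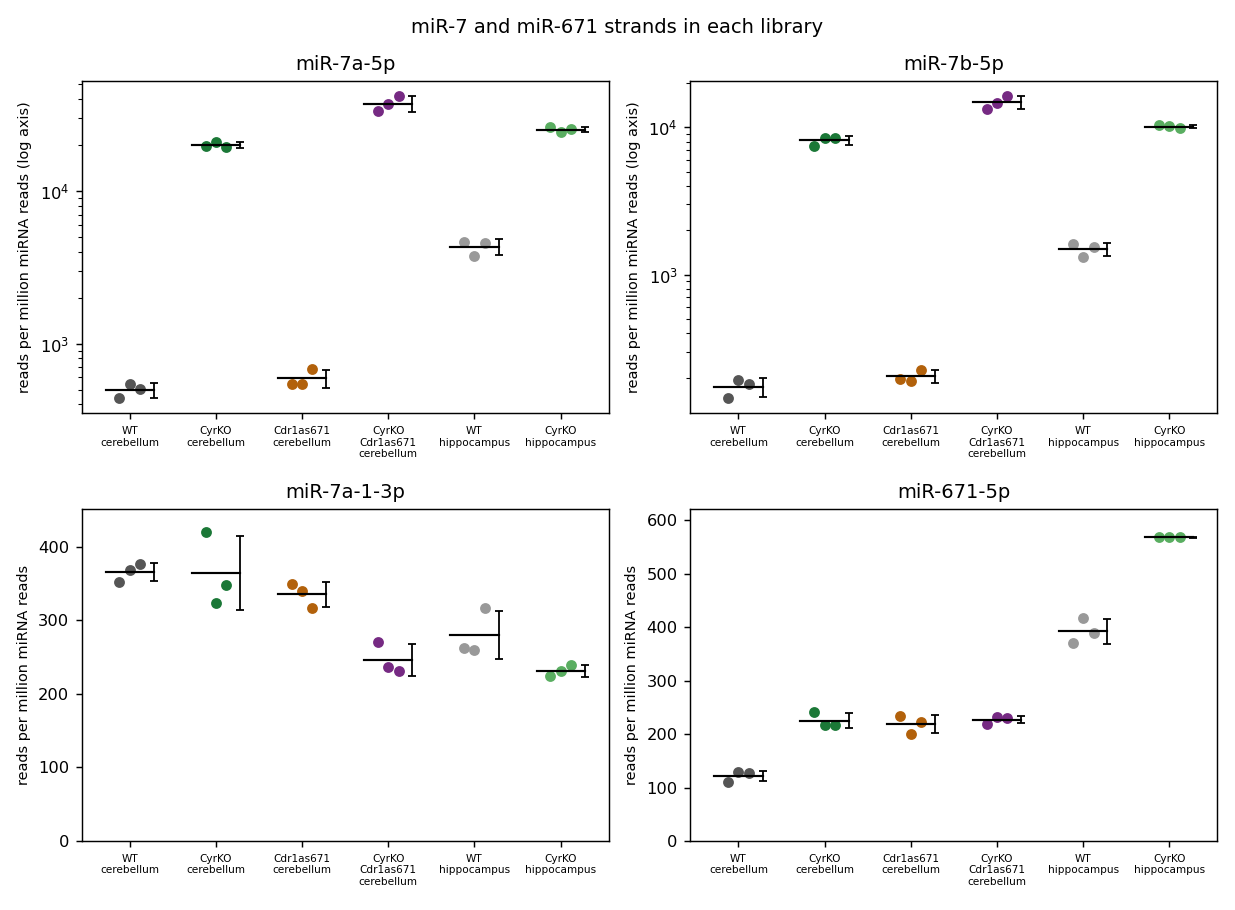
Abundance in CPM of miR-7a-5p and miR-7b-5p (log axes) and of miR-7a-1-3p and miR-671-5p (linear axes from 0) in each library, with the mean and SD of each group of 3. miR-7a-5p averaged 496 CPM in WT and 20026 CPM in CyrKO cerebellum, while miR-7a-1-3p averaged 365 and 364 CPM.

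The hippocampus asks the same question in a tissue with more miR-7. There miR-7a-5p rose 5.77-fold, from 4314 ± 491 CPM in WT to 25224 ± 891 CPM in CyrKO, and miR-7b-5p rose 6.72-fold, from 1485 ± 147 to 10112 ± 227 CPM (SD, n = 3 each). miR-409-3p rose from 172 ± 13.6 to 320 ± 21.9 CPM and miR-671-5p from 392 ± 23.5 to 568 ± 0.65 CPM. The guides took 3.53% ± 0.09 of miRNA reads in CyrKO hippocampus and 2.82% ± 0.12 in CyrKO cerebellum, against 0.580% ± 0.06 and 0.0669% ± 0.0078 in WT. edgeR's QL test called these 4 of 702 miRNAs, with log2 changes of 2.53 (SE 0.10) for miR-7a-5p, 2.75 (SE 0.09) for miR-7b-5p, 0.87 (SE 0.08) for miR-409-3p and 0.52 (SE 0.07, adjusted p = 0.00386) for miR-671-5p, and DESeq2 called 4 that rose and 0 that fell, as edgeR did (27 at an unadjusted p under 0.05 in edgeR, 11 of them lower). Without WT hippocampus library 3 the count was 7. miR-411-3p had a log2 change of 0.24 (SE 0.09) and miR-379-3p of 0.21 (SE 0.10), both with an adjusted p of 0.846. The lowest p among the rest belonged to miR-7066-3p at −0.68 (SE 0.20), miR-1247-5p at 0.39 (SE 0.12) and miR-504-5p at −0.35 (SE 0.11), each with an adjusted p of 0.846. The passenger strands were at −0.29 for miR-7a-1-3p, −0.09 for miR-7a-2-3p and −0.06 for miR-7b-3p, and miR-671-3p was at 0.05, none past the threshold, while adjusted over the list alone 1 of the 3 passenger strands fell.

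In hippocampus 2 lists passed camera although none of their members passed alone. The 6 vessel miRNAs had a median log2 change of 0.23 (adjusted p = 0.0289, and adjusted p = 0.903 with an estimated correlation), with miR-143-5p, a miRNA of vascular smooth muscle, at 0.58 (SE 0.22) and 0 of 6 members past the threshold over all tested or adjusted over the list alone. The 7 let-7 miRNAs, which mark differentiated cells, had a median of −0.19 (adjusted p = 0.0258, and adjusted p = 0.903 with an estimated correlation), with let-7f-5p at −0.22 and again 0 of 7 members past either threshold. The 9 choroid plexus miRNAs had a median of 0.45 that did not pass (camera adjusted p = 0.174), with 8 of 9 positive. Relative to WT their means were 0.04, 0.81 and −0.85 in WT libraries 1, 2 and 3 and −0.15, 0.87 and 0.57 in CyrKO, and WT library 3 also had the highest let-7 mean, 0.18, against −0.06 and −0.13 in WT libraries 1 and 2. The vessel call ended without WT library 1 or 3 or CyrKO library 1 or 2 (adjusted p 0.118, 0.0697, 0.119 and 0.173), and the let-7 call without WT library 3 or CyrKO library 1 or 2 (adjusted p 0.0697, 0.0519 and 0.0767).

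The fold rise of miR-7 in CyrKO was smaller in hippocampus than in cerebellum, although the added reads of both guides together came to 29537 CPM in hippocampus and 27493 CPM in cerebellum, a difference that was not tested. The difference of the log2 changes was −2.82 (SE 0.15) for miR-7a-5p and −2.81 (SE 0.16) for miR-7b-5p, both with an adjusted p of 3.17e-09 by edgeR's QL test over 746 miRNAs. miR-411-3p also differed, at −0.77 (SE 0.16, adjusted p = 0.0387), and these 3 were all that passed. miR-411-3p lost its call with the replicate block (adjusted p = 0.0959), with the choroid plexus covariate (adjusted p = 0.121) and without CyrKO hippocampus library 2 (adjusted p = 0.111), which left 2. miR-409-3p at −0.64 (SE 0.14, adjusted p = 0.0785), miR-379-3p at −0.67 (SE 0.16, adjusted p = 0.083), miR-666-3p at 0.51 (SE 0.15, adjusted p = 0.347) and miR-671-5p at −0.37 (SE 0.13, adjusted p = 0.765) did not pass. The vessel list differed by a median of 0.24 (camera adjusted p = 0.032, and adjusted p = 0.828 with an estimated correlation, 0 of 6 members past the threshold over all tested or adjusted over the list alone). The vessel call also ended without any 1 of WT cerebellum library 1, CyrKO cerebellum libraries 2 and 3, WT hippocampus library 1 and CyrKO hippocampus libraries 1 and 2 (adjusted p from 0.0581 to 0.194).

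The effect of losing Cyrano can be set side by side in pairs of comparisons that share no library. All 4 miRNAs that rose in CyrKO hippocampus also rose in CyrKO cerebellum, where 0.0376 would be shared by independent lists (one-sided Fisher's exact p = 2.19e-09). All 5 that rose in the double mutant against Cdr1as671 rose in CyrKO cerebellum, against 0.0449 for independent lists (Fisher's exact p = 5.49e-12). Fisher's exact test treats miRNAs as independent, which strands that may share reads are not, so both p-values are descriptive. Beyond miR-7 the changes of the remaining miRNAs correlated across miRNAs between tissues at r = −0.02 and rho = −0.18 over 404 miRNAs above 10 CPM, while the pair within cerebellum had r = 0.487 and rho = 0.15 over 406 (miRNAs are not independent replicates). Without the 10 CPM limit the pair within cerebellum had r = 0.26 and rho = 0.06 over 666 miRNAs. The tissues then had r = −0.01 and rho = −0.10 over 636.

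**Figure D2:**
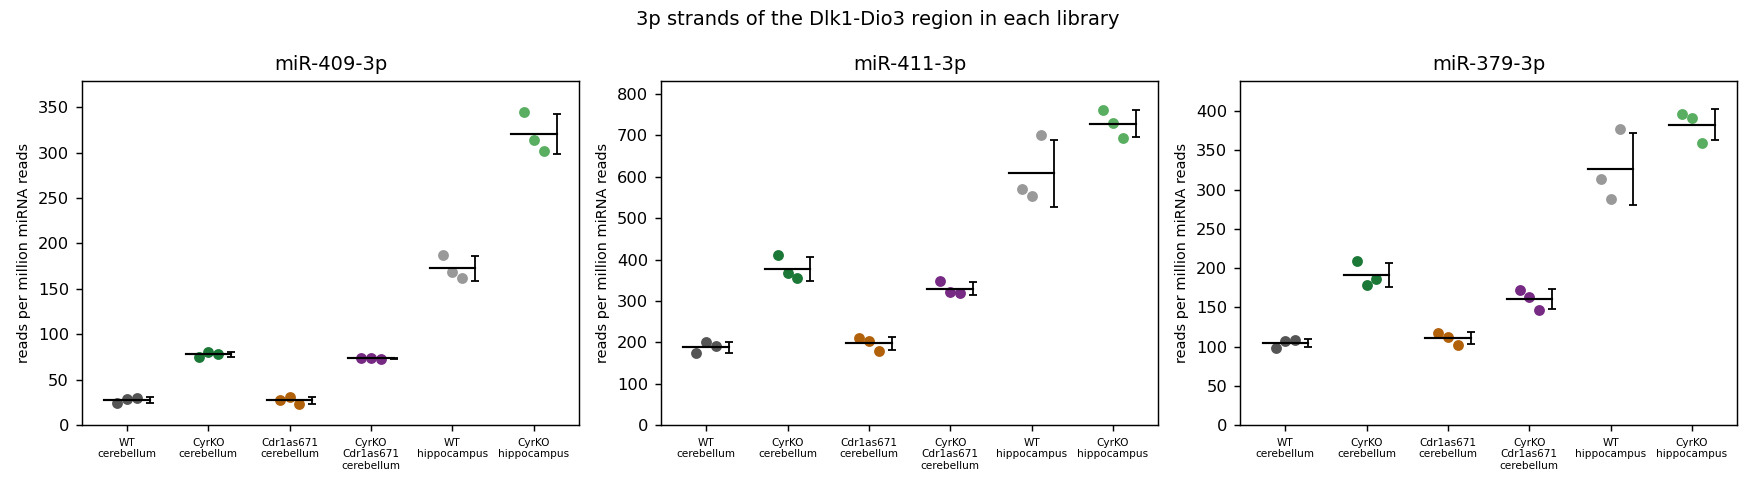
Abundance in CPM (linear axes from 0) of miR-409-3p, miR-411-3p and miR-379-3p in each library, with the mean and SD of each group of 3. miR-409-3p averaged 27.5 CPM in WT and 27.3 CPM in Cdr1as671 cerebellum, and 77.9 and 73.3 CPM in the groups without Cyrano.

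Cdr1as671 mice lack the site by which miR-671 slices Cdr1as, and the comparison with WT cerebellum asks which miRNAs respond. miR-671-5p rose 1.75-fold, from 122 ± 9.55 to 219 ± 16.7 CPM (SD, n = 3 each), while miR-671-3p had a log2 change of −0.08 (SE 0.14). The miR-7 guides did not pass, with 590 ± 80.1 CPM of miR-7a-5p (log2 change 0.22, SE 0.13, adjusted p = 0.36) and 204 ± 19.7 CPM of miR-7b-5p (0.21, SE 0.13, adjusted p = 0.41). miR-7052-3p, miR-466h-3p, miR-574-5p and miR-1224-5p rose by 1.15, 0.86, 0.66 and 0.60 on the log2 scale, the first pair at levels of about 10 CPM or less. Of the 10 that fell, miR-19b-3p and miR-106b-5p belong to the growth-promoting miR-17~92 family, with miR-19b-3p at 2981 ± 148 CPM in WT and 1737 ± 428 CPM in the mutant. miR-409-5p and miR-496a-3p of the miR-379/410 cluster fell by 0.79 and 0.66 on the log2 scale, and miR-511-3p, miR-1197-3p, let-7f-1-3p, miR-130b-3p, miR-544-5p and miR-15b-5p fell by 1.29, 1.23, 0.84, 0.74, 0.72 and 0.71. edgeR's QL test called these 15 of 665 miRNAs, with adjusted p from 0.0125 for miR-671-5p to 0.0498 for miR-1224-5p and miR-15b-5p. The log2 ratio of miR-671-5p to miR-671-3p was 3.42 ± 0.31 against 2.52 ± 0.14 in WT (exact two-sided permutation p = 0.1, adjusted p = 0.107).

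The miR-17~92 group was lower as a set in Cdr1as671 by 1 of its tests. Of its 11 members, 2 fell over all tested, 4 fell adjusted over the list alone, and all 11 had a negative log2 change, with miR-17-5p at −0.83 (SE 0.21, adjusted p = 0.105). The median was −0.63 (camera adjusted p = 0.000244, and adjusted p = 0.899 with an estimated correlation, fry adjusted p = 0.335). Of the 35 tested members of the miR-379/410 cluster, 2 fell over all tested and 5 adjusted over the list alone. Of the 16 neuronal miRNAs 0 passed over all tested by edgeR, while 2 rose and 2 fell adjusted over the list alone. The 3 erythroid miRNAs, markers of red blood cells, set apart 2 of the 3 mutant libraries. Their mean log2 CPM minus the WT mean was −4.42, −4.97 and 0.28 in Cdr1as671 libraries 1, 2 and 3, against −0.12, −1.10 and 1.22 in WT, while the same measure for the miR-17~92 group was −0.82, −0.67 and −0.25 in these 3 libraries. miR-451a averaged 15341 ± 11827 CPM in WT and 4983 ± 7543 CPM in Cdr1as671 (log2 change −1.64, SE 1.65, adjusted p = 0.666), and 0 of 3 erythroid members passed over all tested or adjusted over the list alone.

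The count of 15 rests on single libraries. Without WT library 1, WT library 3 or Cdr1as671 library 1 edgeR called 0 miRNAs (80, 105 and 77 at an unadjusted p under 0.05), without Cdr1as671 library 2 it called 1, and without Cdr1as671 library 3 it called 112, while miR-671-5p kept a log2 change of 0.77 to 0.89 with an adjusted p of up to 0.164. In 1 fit of the 12 cerebellum libraries edgeR called 42 miRNAs, and 1 once the erythroid mean was a covariate in that fit or Cdr1as671 libraries 1 and 2 were left out of it, which leaves 1 library in that group and takes the spread from the other groups. In the 6 libraries DESeq2 called 26, 8 that rose and 18 that fell, while edgeR called 4 with RLE size factors, 3 without the 10 most abundant miRNAs and 3 at a mean of at least 10 CPM.

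**Figure D3:**
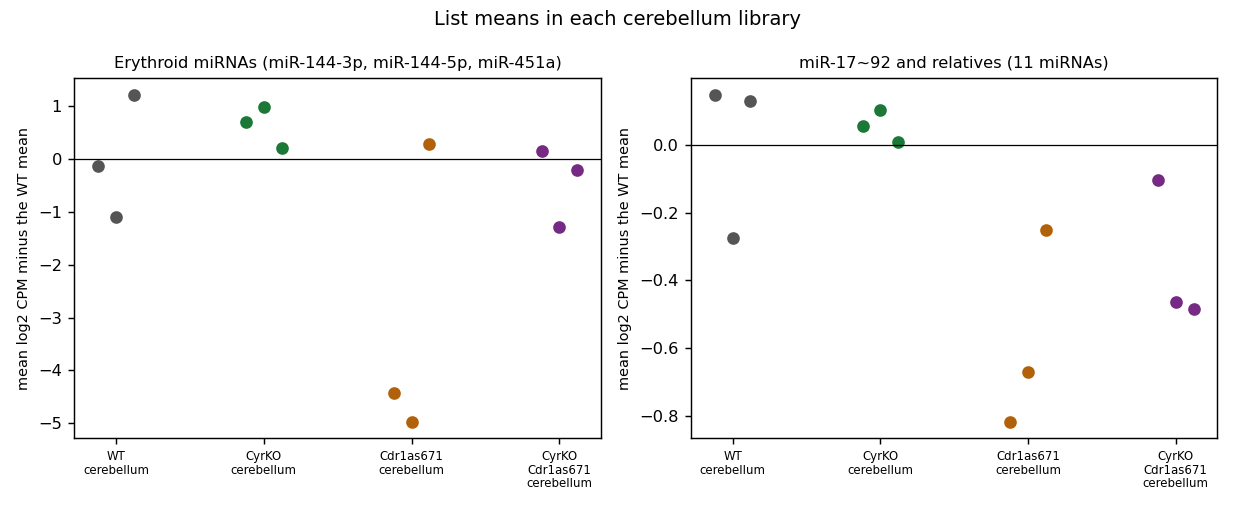
Mean log2 CPM, relative to the WT mean, of the 3 erythroid miRNAs and of the 11 miRNAs of the miR-17~92 group in each cerebellum library (points, 3 per group). Cdr1as671 libraries 1 and 2 lie at −4.42 and −4.97 for the erythroid miRNAs, and library 3 at 0.28.

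The double mutant joins both changes, and its comparison with WT cerebellum gave the highest miR-7 levels of the series. miR-7a-5p rose 79.9-fold to 37299 ± 4214 CPM and miR-7b-5p 90.5-fold to 14745 ± 1442 CPM (SD, n = 3), so that the guides took 5.20% ± 0.57 of miRNA reads. The Dlk1-Dio3 strands miR-409-3p, miR-411-3p and miR-379-3p rose 2.83-fold, 1.85-fold and 1.63-fold, and miR-671-5p rose by 0.98 (SE 0.08) on the log2 scale to 227 ± 6.82 CPM. On the log2 scale other rises included those of miR-466h-3p (0.86), miR-669e-5p (0.74), miR-379-5p (0.54), miR-539-5p (0.45), miR-143-3p (0.41) and miR-431-5p (0.41). miR-409-5p fell by 0.79, miR-3099-3p by 0.50, miR-7a-1-3p by 0.49 (SE 0.08, adjusted p = 0.00717) and miR-346-5p by 0.37 on the log2 scale. miR-671-3p was at −0.25 (SE 0.11, adjusted p = 0.26). edgeR's QL test called 17 of 662 miRNAs, 13 that rose and 4 that fell. With the replicate number as a block it called 35, 16 that rose and 19 that fell, and library totals alone gave 10 and 21. The count was 8, 58 and 6 without WT libraries 1, 2 and 3, and 6 without double-mutant library 2 or 3.

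By list, 3 of 35 tested members of the miR-379/410 cluster rose and 1 fell in the double mutant against WT, and adjusted over the list alone 3 rose and 3 fell. All 11 miR-17~92 members had a negative log2 change, with a median of −0.33 (camera adjusted p = 0.0144, and adjusted p = 0.892 with an estimated correlation), miR-17-5p at −0.64 (SE 0.15), 0 past the threshold over all tested and 2 that fell adjusted over the list alone. The 3 erythroid miRNAs were also all negative, with a median of −0.44 (−0.63 in the edgeR fit) that did not pass (camera adjusted p = 0.665). The miR-17~92 call ended without WT library 3 or double-mutant library 2 (adjusted p 0.0612 and 0.0629). The 3 miR-30 miRNAs had a median of 0.17 (camera adjusted p = 0.0426, and adjusted p = 0.892 with an estimated correlation), with 0 that rose over all tested and 3 adjusted over the list alone, miR-30e-5p being at 0.19 (SE 0.06). Their call ended without WT library 1, 2 or 3 or double-mutant library 2 (adjusted p 0.124, 0.0799, 0.0612 and 0.0629). The 3 miR-183 cluster miRNAs, known from sensory cells, had a median of 0.45 and passed camera only with the replicate block (adjusted p = 0.048, against 0.0985 without it, and 0.892 without it with an estimated correlation), with miR-183-5p at 0.65 (SE 0.17), 0 that rose over all tested and 2 adjusted over the list alone.

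Against CyrKO, the double mutant asks what the Cdr1as mutation adds where Cyrano is already lost. Separate library preparation of the lines with the mutation cannot be told apart from the mutation here. miR-7a-5p rose a further 1.93-fold, from 20026 ± 838 to 37299 ± 4214 CPM, and miR-7b-5p 1.87-fold, while miR-671-5p, at 225 ± 14.1 and 227 ± 6.82 CPM, did not differ (log2 change 0.06, SE 0.10, adjusted p = 0.748). The passenger strand miR-7a-1-3p fell by 0.52 (SE 0.10, adjusted p = 0.0104) on the log2 scale. miR-143-3p of vascular smooth muscle rose by 0.56, as did miR-466h-3p, miR-379-5p, miR-330-5p and miR-1843a-5p by 0.79, 0.52, 0.51 and 0.47. let-7b-3p, miR-409-5p, miR-199a-5p, miR-130b-3p and miR-3099-3p fell by 0.87, 0.83, 0.71, 0.68 and 0.64, and miR-494-3p, miR-496a-3p and miR-337-3p by 0.57, 0.50 and 0.44. edgeR's QL test called these 16 of 688 miRNAs, 7 that rose and 9 that fell, with an adjusted p of 0.000389 for both miR-7 guides. The count was 7 and 9 without CyrKO libraries 1 and 3, and 26, 9 and 2 without double-mutant libraries 1, 2 and 3.

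In the miR-379/410 cluster 1 of 35 members rose and 3 fell in the double mutant against CyrKO, and adjusted over the list alone 2 rose and 3 fell. All 11 miR-17~92 members again had a negative log2 change, with miR-17-5p at −0.61, a median of −0.38 (camera adjusted p = 0.00349, and adjusted p = 0.734 with an estimated correlation), 0 past the threshold over all tested and 2 that fell adjusted over the list alone. The 3 erythroid miRNAs were also all negative here, with a median of −1.06 that did not pass (camera adjusted p = 0.521), and their means relative to WT were 0.16, −1.29 and −0.20 in double-mutant libraries 1, 2 and 3, each below the 0.71, 1.00 and 0.21 of the CyrKO libraries. The miR-17~92 call ended without CyrKO library 2 (adjusted p = 0.0643). The changes in Cdr1as671 against WT and in the double mutant against CyrKO, which share no library, correlated at r = 0.702 and rho = 0.656 over 407 miRNAs above 10 CPM without the miR-7 guides, and 75.9% had the same sign (miRNAs are not independent replicates). All 15 miRNAs called in Cdr1as671 had the same direction in the other comparison. The shared calls were miR-466h-3p among those that rose (0.0526 for independent lists, one-sided Fisher's exact p = 0.0517) and miR-130b-3p, miR-409-5p and miR-496a-3p among those that fell (0.135 for independent lists, Fisher's exact p = 0.000197). Fisher's exact test treats miRNAs as independent, so these p-values too are descriptive.

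Against Cdr1as671, the double mutant shows what Cyrano loss adds where the Cdr1as site is already mutated. miR-7b-5p rose by 6.28 (SE 0.15) and miR-7a-5p by 6.08 (SE 0.15) on the log2 scale, and miR-409-3p, miR-411-3p and miR-379-3p rose by 1.54 (SE 0.11), 0.85 (SE 0.09) and 0.65 (SE 0.10). These 5 of 688 miRNAs passed edgeR's QL test, with adjusted p from 7.71e-15 for miR-7b-5p to 0.000798 for miR-379-3p, and none fell in edgeR (0 of 688, with 59 at an unadjusted p under 0.05, 22 of them lower) or in DESeq2 (5 that rose and 0 that fell). miR-671-5p was at 0.16 (SE 0.10, adjusted p = 0.647). The count was 59 without Cdr1as671 library 3, and 8 scaled by library totals alone, where 3 fell and the median of all miRNAs was −0.12.

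The interaction asks whether the double mutant differs from the sum of both single changes on the log2 scale. miR-671-5p was the 1 miRNA of 688 past the threshold, at −0.75 (SE 0.14, adjusted p = 0.043), with 219 CPM in Cdr1as671, 225 CPM in CyrKO and 227 CPM in the double mutant. The miR-7 guides had positive values that did not pass, 0.73 (SE 0.17) for miR-7a-5p and 0.70 (SE 0.17) for miR-7b-5p, each with an adjusted p of 0.168 by edgeR's QL test over all tested, while adjusted over the list alone both rose, and miR-666-3p was at 0.46 (SE 0.11, adjusted p = 0.18). miR-671-5p lost its call with the replicate block (adjusted p = 0.101), with a filter at 10 CPM (adjusted p = 0.0569), and in 10 of the 12 fits that left out 1 cerebellum library, the exceptions being Cdr1as671 libraries 2 and 3. Without Cdr1as671 library 3, 19 miRNAs passed, among them both miR-7 guides.

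WT hippocampus and WT cerebellum differed widely, which sets the levels against which the mutants are read. miR-206-3p, a muscle miRNA, fell from 901 ± 65.2 CPM in cerebellum to 5.77 ± 1.15 CPM in hippocampus, and miR-216a-5p, miR-216b-5p and miR-217-5p, neighbours best known from pancreas, were lower in hippocampus 90.3-fold, 130-fold and 140-fold. miR-137-3p, a regulator of synaptic genes, rose from 613 ± 29.0 to 10596 ± 295 CPM. miR-344d-3p, miR-551b-3p, miR-3085-3p, miR-3059-5p, miR-139-3p and miR-139-5p rose by 5.14, 4.06, 3.48, 2.99, 2.94 and 2.77, miR-195a-5p, miR-497-5p and miR-194-5p fell by 2.88, 2.58 and 2.52, and miR-497-3p was 15-fold lower. miR-7a-5p rose by 2.57 (SE 0.11) and miR-7b-5p by 2.55 (SE 0.12), while the passenger strands went apart, miR-7a-2-3p rising by 4.51 (SE 0.16), miR-7a-1-3p falling by 0.93 (SE 0.11) and miR-7b-3p at −0.21 (SE 0.21). miR-671-5p rose by 1.13 (SE 0.09) and miR-671-3p was at 0.05 (SE 0.11). edgeR's QL test called 522 of 746 miRNAs, 280 that rose and 242 that fell. In CPM, which is scaled by library totals and not by TMM, 72.0% did not overlap between the groups, where chance gives 10%. Scaled by library totals alone the median of all miRNAs was 0.58, and 402 rose and 126 fell, so directions here are relative to the bulk of miRNAs.

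**Figure D4:**
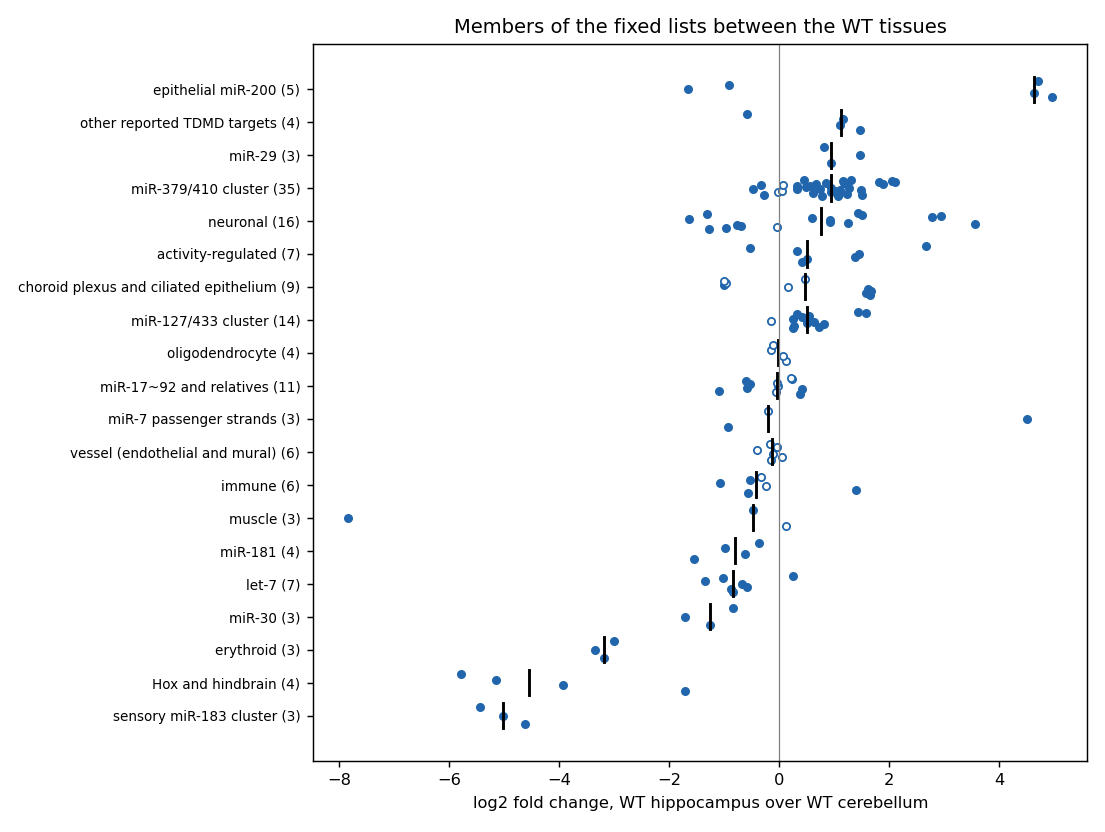
Log2 fold change of WT hippocampus over WT cerebellum for the members of each list with at least 3 tested (number in brackets, filled points past the adjusted threshold, bars at the median). The miR-183 list lies at a median of −5.05 by its list test, and 29 of 35 members of the miR-379/410 list rose.

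By list, all 3 miR-183 cluster miRNAs fell between the tissues (median −5.05), as did all 4 Hox and hindbrain miRNAs (−4.21), which follow position along the body axis, with miR-10b-5p at −3.94 and miR-196a-5p at −5.15. In the imprinted clusters 29 of 35 miR-379/410 members rose and 3 fell (median 0.93), miR-409-3p by 2.10, and 13 of 14 members of the miR-127 and miR-433 cluster rose (0.49). All 3 miR-29 members rose (0.95), all 3 miR-30 (−1.27) and all 4 miR-181 (−0.80) fell, and 1 let-7 member rose while 6 fell (−0.86). These 8 lists passed camera, with adjusted p of 1.12e-05 for miR-379/410, 0.0353 for miR-29 and 0.0226 for the other 6. None held with an estimated correlation (adjusted p = 0.365 with an estimated correlation for miR-183, Hox, miR-379/410, miR-29, miR-30 and miR-181, and 0.404 for let-7 and the cluster of miR-127 and miR-433). Counts adjusted over the list alone were the same for these 8 lists.

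The other lists did not pass camera between the WT tissues. Of 16 neuronal miRNAs 9 rose and 6 fell, and of 7 activity-regulated miRNAs 6 rose and 1 fell, with miR-212-3p up by 1.37 and miR-188-5p down by 0.54. All 3 erythroid miRNAs fell, miR-451a by 3.19 and miR-144-3p by 3.35. Epithelial miR-200a-3p, miR-200b-3p and miR-429-3p rose by 4.96, 4.64 and 4.71 while the other 2 of that list fell. Of 9 choroid plexus miRNAs 4 rose and 1 fell over all tested, but 0 rose and 1 fell adjusted over the list alone. Of 6 immune miRNAs 1 rose and 3 fell, miR-146a-5p up by 1.39 and miR-155-5p down by 1.07, and 2 of 3 muscle miRNAs fell. Of 4 other reported targets of target-directed degradation 3 rose and 1 fell, miR-29b-3p by 1.47 and miR-16-1-3p at −0.59, and of 11 miR-17~92 members 2 rose and 4 fell. The endocrine miR-375-3p rose by 1.82. None of the 4 oligodendrocyte and 6 vessel miRNAs passed in edgeR (0 each, where 544 of all 746 had an unadjusted p under 0.05). Apart from the choroid plexus list, the counts adjusted over the list alone were the same. With library totals alone the medians of the passenger strand, oligodendrocyte, immune, vessel, muscle and miR-17~92 lists became positive. The entries that overlap rRNA passed the count filter in no comparison.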

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

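The tests of the whole cluster, of miR-7 reads in both tissues and in the double mutant, of the Cdr1as671 genotype, of partner miRNAs of red blood cells and with the erythroid covariate were chosen after the result was seen.

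The rise of miR-7 without Cyrano differed between the tissues by a test of the difference itself, with a log2 difference of hippocampus minus cerebellum of −2.82 (SE 0.15, adjusted p = 3.17e-09) for miR-7a-5p. For miR-7b-5p the difference was −2.81 (SE 0.16, adjusted p = 3.17e-09). miR-411-3p also differed between the tissues, by −0.77 (SE 0.16, adjusted p = 0.0387). In the interaction of both mutations in cerebellum miR-671-5p was at −0.75 (SE 0.14, adjusted p = 0.043). Of 100 splits of the 12 libraries, the real one included, 7 gave at least 3 miRNAs for the tissue difference (highest other count 6). For the interaction 5 gave at least 1 (highest other count 1). Libraries were shuffled within each tissue for the first and over all cerebellum groups for the second. Other splits can therefore carry part of the real CyrKO effect. The splits cannot decide on chance, which is not excluded for either count.

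miR-409-3p, miR-411-3p and miR-379-3p were higher without Cyrano in cerebellum, while the other 34 tested members of the miR-379/410 list had a median log2 change of 0.0364 (SD 0.0942, highest 0.268) against 0.876 for the smallest of the 3 rises, which argues against a change of the whole cluster. As to a highly complementary site in Cyrano, the 3 arms had a median percentile of 27.2, where miR-7a-5p and miR-7b-5p ranked at 98.2 and 97.6. The score can grow with the length of the arm. The hairpins of the 3 are 66 to 82 nt long and those of miR-7 97 to 111 nt, so this ranking cannot decide on such a site. For miR-7 reads counted to these miRNAs, the added reads per added miR-7 read in hippocampus had a median of 0.608 (SE 0.318) relative to cerebellum, inside the range from 0.5 to 2 that this explanation allows, but miR-409-3p, the 1 of the 3 called there, lay above it at 2.73 (SE 0.318), while miR-411-3p at 0.592 and miR-379-3p at 0.608 were not called there. In the double mutant, a test chosen after its values had been seen, the median was 0.376 (SE 0.0577), below that range. That value was of miR-411-3p, with miR-379-3p at 0.309 (SE 0.0662). miR-409-3p at 0.490 (SE 0.0484) lay within 1 SE of the lower bound. A response to the loss of Cyrano stays open as untested, and the origin of single reads was not analysed here.

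miR-144 and miR-451a were far lower in Cdr1as671 libraries 1 and 2, and 15 miRNAs were called in that group against WT. The Cdr1as671 genotype as a cause of a low erythroid level in every library is argued against by 3 of the 6 libraries with the mutation, which lay inside the WT range. Cdr1as671 library 3, part of the pattern that prompted the test, is among them. Cdr1as671 libraries 1 and 2 and double-mutant library 2 lay below that range (−4.42, −4.97 and −1.29 relative to the WT mean, lowest WT library −1.10). A lower share of red blood cells may account for the low erythroid level, and 100% of the partner miRNAs were also lower. These were only 2, miR-142-3p at −1.83 and miR-142-5p at −2.25, too few to decide. They were picked because they moved with the erythroid mean, which does not single out red blood cells. Red blood cell content as the cause of the 15 calls cannot be told apart from the genotype. With the erythroid mean as covariate the median absolute change went from 0.786 to 0.627. The ratio, 0.798, is too near the bound of 0.75 set for it. Its SD over 1000 resamplings of the called miRNAs was 0.105, which leaves out variation between libraries. With the covariate 1 call was left, miR-671-5p at 0.88 (adjusted p = 0.00101), while the median SE went from 0.170 to 0.189 and 15 of 15 kept their sign.

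The log2 changes of Cdr1as671 against WT and of the double mutant against CyrKO, whose contrasted groups share no library, correlated across miRNAs, most of them not called. Red blood cell content cannot be told apart from the mutation here. The ratio of the correlation with the erythroid covariate to that without it was 1.04 (SD 0.0531) in 1 fit. There a shared slope adds correlation by itself. With each comparison fitted on its own libraries the ratio was 0.497 (SD 0.263). In those fits r was 0.331 with and 0.666 without the covariate over 404 miRNAs. Each SD is over 1000 resamplings of the miRNAs, which leaves out variation between libraries. Separate library preparation of the lines with the mutation cannot be told apart from the mutation, since every library with it would share the batch. The miRNA reads took 35.2% to 37.6% of the number in the sample description in those libraries and 40.1% to 43.8% in the other cerebellum libraries, a gap of 2.58 percentage points, and the labels do not say what that number counts. The mutation itself stays open as a cause.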

How the results depend on the processing

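The erythroid covariate, the choroid plexus covariate and the fits without Cdr1as671 libraries 1 and 2 were chosen after the result was seen. The rises of miR-7a-5p and miR-7b-5p without Cyrano kept direction and threshold under every alternative run, and the limits lie in the comparisons with Cdr1as671 and in the contrasts of effects. Over miR-7a-5p, miR-7b-5p and miR-671-5p, 242 of the values from alternatives other than leaving out 1 library kept their direction and side of the threshold, 2 gained and 2 lost a call, and none reversed. When 1 library was left out, 237 kept theirs, 2 gained and 13 lost a call. Depth limits passenger strands of few reads, and with 1 library left out of 3 the tests have less power. Except where fewer miRNAs or libraries were tested, the cause of a difference was not tested.

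For Cdr1as671 against WT, where 15 miRNAs passed, DESeq2 gave 26 (8 higher, 18 lower), RLE size factors 4 (2 and 2), leaving out the 10 most abundant miRNAs 3 (1 and 2), no low-count filter 53 (17 and 36), a mean of at least 10 CPM 3 (1 and 2), the replicate block 42 (7 and 35), 12 libraries in 1 fit 42 (13 and 29), the authors' deposited test gave 26 (7 and 19), the erythroid covariate 1, and Cdr1as671 libraries 1 and 2 left out 1. The covariate was added to the fit of 12 libraries, and the last fit holds 1 Cdr1as671 library, assumed to vary like the other groups, so fewer calls are partly built in. For the double mutant against WT, where 17 passed, DESeq2 gave 44 (20 and 24), library totals 31 (10 and 21), no filter 61 (29 and 32), the block 35 (16 and 19), the authors' deposited test gave 43 (19 and 24) and the erythroid covariate 29 (15 and 14). Against CyrKO, where 16 passed, DESeq2 gave 33 (16 and 17), library totals 25 (7 and 18) and no filter 26 (11 and 15). Against Cdr1as671, where 5 passed, library totals gave 8 (5 and 3). The interaction, with 1, had 2 in DESeq2, 4 with no filter, and in edgeR 0 at a mean of at least 10 CPM (17 at an unadjusted p under 0.05) and 0 with the block (28 at an unadjusted p under 0.05). The tissue difference, with 3, had 5 in DESeq2 and 5 without the 10 most abundant miRNAs, 4 with no filter and 4 at 10 CPM, and 2 with the block, with the choroid plexus covariate and without CyrKO hippocampus library 2, where miR-411-3p did not pass. In CyrKO against WT cerebellum 6 rose in each alternative, and 1 miRNA was lower with no filter, with the block, with 12 libraries in 1 fit and with the erythroid covariate.

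In the interaction with no filter miR-7a-5p was at 0.73 and miR-7b-5p at 0.71 (adjusted p = 0.00494 each, and 0.168 with the filter), and miR-671-5p was at −0.71 with the filter at 10 CPM and −0.74 with the block. Values near 0 changed sign. miR-7a-1-3p in CyrKO against WT cerebellum, −0.0045, was 0.0112 in DESeq2, 0.0141 with RLE size factors, 0.0116 without the 10 most abundant miRNAs, 0.0198 with no filter, 0.0221 at 10 CPM, 0.0135 with 12 libraries, 0.0112 in the authors' table and 0.0102 with the erythroid covariate. With Cdr1as671 libraries 1 and 2 left out, miR-7b-3p in Cdr1as671 against WT was −0.25, and miR-671-3p was 0.0619 in the double mutant against Cdr1as671 and 0.19 in the interaction (0.0469 with the erythroid covariate). With library totals miR-7a-2-3p in the double mutant was −0.0079 against WT and −0.0381 against CyrKO, and miR-7b-3p between the WT tissues was 0.33. miR-7b-3p in the tissue difference was −0.0303 without the 10 most abundant miRNAs, −0.0394 at 10 CPM and −0.0418 with the block, and miR-671-3p between the WT tissues at 10 CPM was −0.0179.

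With 1 library left out, the lowest and highest counts were 4 and 7 for CyrKO against WT in hippocampus (7 without WT library 3), 0 and 112 for Cdr1as671 against WT in edgeR (0 without WT library 1, WT library 3 or Cdr1as671 library 1, with 80, 105 and 77 at an unadjusted p under 0.05, 1 without Cdr1as671 library 2 and 112 without library 3), 6 and 58 for the double mutant against WT (8, 58 and 6 without WT libraries 1, 2 and 3, 6 without double-mutant library 2 or 3), 2 and 26 against CyrKO (7 and 9 without CyrKO libraries 1 and 3, 26, 9 and 2 without double-mutant libraries 1, 2 and 3), 5 and 59 against Cdr1as671 (59 without Cdr1as671 library 3), and 0 and 19 for the interaction in edgeR (19 without Cdr1as671 library 3, 1 without library 2, and 0 without any other, with 19 to 48 at an unadjusted p under 0.05). The log2 ranges in CyrKO against WT cerebellum were −0.10 to 0.0702 for miR-7a-1-3p, −0.0665 to 0.21 for miR-7a-2-3p and −0.33 to 0.34 for miR-7b-3p, and in hippocampus −0.12 to 0.01 for miR-7b-3p. In Cdr1as671 against WT they were −0.20 to 0.48 for miR-7b-3p, 0.77 to 0.89 for miR-671-5p and −0.16 to 0.0393 for miR-671-3p, and in the double mutant against CyrKO −0.0895 to 0.14 for miR-7a-2-3p. In the interaction they were 0.65 to 0.95 for miR-7a-5p, 0.64 to 0.89 for miR-7b-5p, −0.82 to −0.63 for miR-671-5p and −0.11 to 0.0749 for miR-671-3p. In the tissue difference they were −0.33 to 0.0045 for miR-7a-2-3p and −0.43 to 0.20 for miR-7b-3p, and between the WT tissues −0.38 to 0.19 for miR-7b-3p. The log2 ratio of miR-7b strands in Cdr1as671 less WT ranged from −0.22 to 0.42.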

Other observations

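No test in this part was chosen after the result was seen except the shorter window in Cyrano.

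The ratio of guide to passenger strand of miR-7 was higher in every group without Cyrano than in its WT group. In Cdr1as671, which keeps Cyrano, the log2 ratios of miR-7a-5p to miR-7a-1-3p and to miR-7a-2-3p were also higher than in WT. The differences there were smaller, 0.375 and 0.371. In hippocampus the log2 ratio of miR-7a-5p to miR-7a-1-3p was 3.95 ± 0.17 in WT and 6.77 ± 0.08 in CyrKO (SD, n = 3 each), and in the double mutant it was 7.24 ± 0.28. miR-671-5p over miR-671-3p was 3.61 ± 0.10 in WT and 4.08 ± 0.16 in CyrKO hippocampus, and 3.76 ± 0.07 in the double mutant. Each of 15 of the 16 ratio comparisons with WT had an exact two-sided permutation p of 0.1, the smallest possible, and the exception was miR-7b in Cdr1as671, with a difference of 0.08 and p = 1.

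In complementarity to the Cyrano transcript the hairpin arm of miR-671-5p ranked at percentile 96.1. That score can grow with the length of the arm, and the Mir671 hairpin is 98 nt long. The rank therefore cannot decide on a site for miR-671 in Cyrano. The best alignments of the arms of miR-7a-5p and miR-7b-5p covered positions 2927 to 2984 and 2932 to 2980. These spans are of the whole arm and not of the mature strand. In a window of 24 nt the percentiles of miR-409-3p, miR-379-3p and miR-411-3p were 62.5, 22.3 and 4.16, against 30.2, 27.2 and 12.5 over the whole arm. Percentiles in that window are not given here for miR-671-5p and the miR-7 guides.

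The splits of the 6 libraries of each comparison of 3 against 3 are 10, the real one included, too few for a share under 0.05, and in each the real split was the 1 of 10 with as many miRNAs. The real and highest other counts were 6 and 1 for CyrKO against WT in cerebellum, 4 and 1 in hippocampus, 15 and 1 for Cdr1as671 against WT, 17 and 0 for the double mutant against WT, 16 and 0 against CyrKO, 5 and 3 against Cdr1as671, and 522 and 0 for the WT tissues.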
